A study of Mus musculus with 11 samples.

How the data were processed

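RNA of 6 marginal and 5 transitional E-mu-BRD2 lymphomas was hybridised to expression arrays, 1 array for each sample. Per the labels' protocols, total RNA was isolated with guanidinium thiocyanate and acid phenol, and biotin-labelled cRNA was transcribed from cDNA primed with poly-dT, so probe sets far from the 3-prime end depend on RNA integrity. The values are array intensities on a linear scale, computed with MAS5 per the submitters' processing notes, and were used as deposited. The MAS5 version is not given in the sources used here. The 2% trimmed mean of the deposited intensities is equal on all 11 arrays (500.2), as MAS5 scaling to a common target gives. A common scale fixes the trimmed mean of each array, so a change of most transcripts in 1 direction would not be seen. No batch or scan record was used, so a batch effect could not be tested, and the labels give no animal numbers. The p-values therefore measure the spread between these samples.

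The table held 22690 probe sets. The 64 Affymetrix control probe sets were left out, 16 was added to each signal before log2, and the upper 60% of the remaining 22626 by mean over all arrays, blind to class, were tested (13576). No pair of arrays held identical values, and 0 columns of the table lacked a sample. Gene symbols came from GEO's platform annotation, updated through Entrez identifiers to a RefSeq gene table of assembly GRCm38.p6. Of the 22626 probe sets, 20380 had 1 gene, 691 several and 1555 none in that annotation, and genes were named only from probe sets with 1 gene. The tested probe sets covered 7740 genes. No genome sequence was used and no coordinates are printed.

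Classes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p 0.05). Spleen grade, the word recorded for each animal, was ranked from 1 to 5 and tested as a linear trend, alone and with class in the model. Gene lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated for each list, and with fry. For each gene of a list the probe set with the highest mean was used. Camera compares a list with all other genes, while fry asks whether the genes of a list move, on balance, in 1 direction. Camera with the preset correlation called 9 of 37 lists between classes, 6 up and 3 down, and 0 of these calls held with an estimated correlation (smallest adjusted p = 0.382) or in fry (smallest adjusted p = 0.626, and 0 for its mixed test). Of 40 lists with 703 genes, 594 genes were on the array and 482 were tested. The skeletal muscle and adipocyte lists had 2 tested genes each and the liver list 0, and these were not tested. Some genes stand in more than 1 list, for example Cr2 in 4 lists of B cells and stroma. Array quality was compared with exact permutation tests over the 462 splits of the arrays.

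The groups, the tests, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Brd2. With fewer than 5 probe sets past the threshold in a direction it takes the 8 with the smallest p, 1 per gene. It takes the 2 members with the smallest p of each described list and the 5 smallest p in each direction for the grade trend. It also takes the 5 immunoglobulin probe sets with the widest range, as run 1 per gene symbol. Alternatives covered the offset (1 and 64), quantile normalization, median scaling, no filter and the upper 40%, eBayes without trend, array weights, the sample number as a block (where marginal 6, with no partner, adds nothing to the class difference), only animals that failed to nest (2 marginal and 5 transitional), the mean of all probe sets of a gene, and leaving out each array in turn. Chosen after the first results were seen were the fit without transitional 4 and 5, covariates for the erythroid score and for sex read from Y-linked transcripts, spleen grade as unordered groups, its interaction with class, list tests of the grade trends, and the estimated correlation in the settings other than the planned one.

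The fits were tested on simulated data. With 100 probe sets changed 2-fold and 100 changed 4-fold, the class comparison recovered 26 and 69 of them under independent noise, with 8 false calls. It recovered 5 and 54 when the residuals of these arrays were used. Those residuals were centred within each class, so the 0 false calls were fixed in advance and each change was estimated at its seeded size. Under independent noise, a shift of 1 log2 unit seeded in the 27 genes of the mitosis list was called by camera (adjusted p = 9.77e-15), with 1 of the 36 other lists also called. Such noise holds no correlation between genes, so this does not show how the preset correlation fares on these arrays.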

Results

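The series followed B cell lymphomas that arise sporadically in E-mu-BRD2 mice, which carry BRD2, a bromodomain protein of the BET family that binds acetylated histones, as a transgene driven by the immunoglobulin heavy chain enhancer in B cells. The mice were on the FVB background, and the tumours were classed by disease severity. RNA from 6 lymphomas of the marginal class and 5 of the transitional class was measured, with 1 array per lymphoma. A further severity class and the resting and activated B cells that the design names are not analysed here. All 11 tumours were recorded as oligoclonal for immunoglobulin. Failure to nest was the recorded sign in 5 of 5 transitional and 2 of 6 marginal animals, so this sign ran with class. Spleen enlargement was graded marginal in marginal 1, mild in marginal 2, 3 and 4 and in transitional 3, moderate in marginal 5 and 6, moderately severe in transitional 4 and 5, and severe in transitional 1 and 2. The tissue from which each tumour RNA was taken is not given in the sources used here. Each array held signals for 22690 probe sets, and the median signal ran from 98.8 on transitional 5 to 151 on transitional 2. Differences below are transitional minus marginal on the log2(signal + 16) scale, which understates those of dim probe sets. The number of arrays limits their precision.

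Mouse Brd2 was measured by 2 tested probe sets. For the brighter the signal was 2900 ± 574 in marginal (SD, n = 6) and 2445 ± 478 in transitional lymphomas (SD, n = 5), a log2 difference of −0.24 with a standard error of 0.19. Its lowest signal was 1844 on transitional 4 and its highest 3504 on marginal 4. For the dimmer the signal was 805 ± 228 (SD, n = 6) and 658 ± 149 (SD, n = 5), a log2 difference of −0.27 with a standard error of 0.23, and the arrays ran from 486 on transitional 4 to 1221 on marginal 4. Neither probe set passed the limma test between classes (adjusted p = 0.999). The species of the transgene is not given in the sources used here, and whether these probe sets read its transcript was not tested. Of the 11 tested members of the BET family and chromatin partners list, 8 had a lower and 3 a higher mean in transitional lymphomas, with a mean log2 difference of −0.24 (camera adjusted p = 0.0666, but 0.0275 without marginal 3, 0.0383 without transitional 5 and 0.0343 with the mean of all probe sets of a gene). With an estimated correlation these 3 settings gave adjusted p = 0.3315, 0.5415 and 0.357. Its members with the smallest p were Crebbp, a histone acetyltransferase, at −0.96 (SE 0.34), and Cdk9, the kinase of the elongation factor P-TEFb, at −0.42 (SE 0.15). Cdk9 signal on each of the 5 transitional arrays lay below that of every marginal array, and neither gene passed the test (adjusted p = 0.999).

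The design divides the lymphomas by severity, and the classes were compared first for genes of B cell identity. All 17 tested members of that list had a lower mean in transitional than in marginal lymphomas, by a mean log2 difference of −1.05. Ebf1, a transcription factor that specifies the B lineage, had a signal of 1691 in marginal and 566 in transitional lymphomas (log2 difference −1.76, SE 0.51), and Cr2, the complement receptor CD21, differed by −1.75 (SE 0.70). The follicular B cell list was lower in 9 of 9 tested members, by −1.02 on average, with S1pr1, a receptor that guides lymphocytes out of tissue, at −1.23 (SE 0.47). Camera with a preset correlation called both lists lower in transitional lymphomas (adjusted p = 1.6e-08 for B cell identity and adjusted p = 0.000118 for follicular B cells). With an estimated correlation neither call held (adjusted p = 0.504 and adjusted p = 0.492, respectively). The B cell identity score, the mean log2 deviation of its members from the 11-array mean, was −1.71 on transitional 4 and −1.98 on transitional 5. It ran from −0.11 to 0.62 on transitional 1, 2 and 3 and from −0.34 to 1.15 on the marginal arrays. Transitional 4 and 5 also had the highest erythroid scores, 2.22 and 1.91, and the lowest natural killer scores, −1.13 and −1.63. Over the 11 arrays B cell identity ran against the erythroid score without passing (Pearson r = −0.581, permutation p = 0.0612; Spearman rho = −0.573, permutation p = 0.0714; r = −0.542 without transitional 1 and 4, and −0.685 within the marginal class). It was 1 of 6 such relations, with adjusted permutation p = 0.0612 and 0.0714. Without transitional 4 and 5, a setting chosen after the data were seen, the mean difference of B cell identity was −0.20 (adjusted p = 0.244) and that of follicular B cells −0.45 (adjusted p = 0.105). With the erythroid score as a covariate, also chosen afterwards, they were −1.45 (adjusted p = 2.52e-11) and −1.31 (adjusted p = 0.000334), each with adjusted p = 0.386 with an estimated correlation.

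Other lists of B cell states did not pass camera over all arrays as deposited. B1 and marginal zone B cell genes had a mean log2 difference of −0.43 with 12 of 14 members lower (adjusted p = 0.232), led by Cr2 and by Dtx1, a regulator of Notch signalling, at −1.26 (SE 0.65). Plasma cell genes had a mean of −0.25 with 9 of 13 members lower (adjusted p = 0.473). The plasma cell members with the smallest p were Tnfrsf13b, the receptor TACI, at −1.10 (SE 0.54), and Irf4 at −0.84 (SE 0.48), whose log2 signal was 6.86 on transitional 4 and at least 9.56 on the other transitional arrays. The germinal centre list had a mean of −0.03 (adjusted p = 0.839), with Fas at 0.89 (SE 0.63) and Bcl6 at −0.37 (SE 0.55), and the pro-B and pre-B list a mean of −0.08 (adjusted p = 0.721), with Cd93 at 0.60 (SE 0.54) and Vpreb3 at −0.63 (SE 0.78). For both of these lists the mean and the median were negative while camera, which sets a list against all other genes, pointed up. Class II antigen presentation genes were lower in 8 of 9 members, by −0.43 on average (adjusted p = 0.121), with the invariant chain Cd74 at −0.48 (SE 0.35) and H2-DMb2 at −0.65 (SE 0.50). Class II was called after quantile normalization (adjusted p = 0.0150) and median scaling (adjusted p = 0.0374) and on leaving out marginal 1 (adjusted p = 0.0460) or transitional 3 (adjusted p = 0.00541). Class I antigen presentation genes were lower in 9 of 10 members, by −0.20 (adjusted p = 0.516), with H2-K1 at −0.35 (SE 0.44) and B2m at −0.20 (SE 0.26). The small germinal centre and pro-B and pre-B means turned sign in several settings. Median scaling gave 0.08 and 0.02 for them, and no filter gave 0.06 and 0.02. The directions of the other lists depended on transitional 4 and 5. Without those arrays the means were 0.20 for B1 and marginal zone B cells, 0.35 for plasma cells, 0.15 for germinal centre, 0.30 for pro-B and pre-B and 0.40 for class II genes, none of which passed, and 0.61 for class I genes (adjusted p = 3.91e-05). With the erythroid score as a covariate class I was instead called lower, at −0.57 (adjusted p = 0.00798), and so was class II, at −0.82 (adjusted p = 0.00177). The plasma cell mean was −0.51 (adjusted p = 0.0426) without transitional 1 and 0.011 without transitional 4. None of the calls for class II, class I and plasma cell genes held with an estimated correlation (smallest adjusted p = 0.469).

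**Figure D1:**
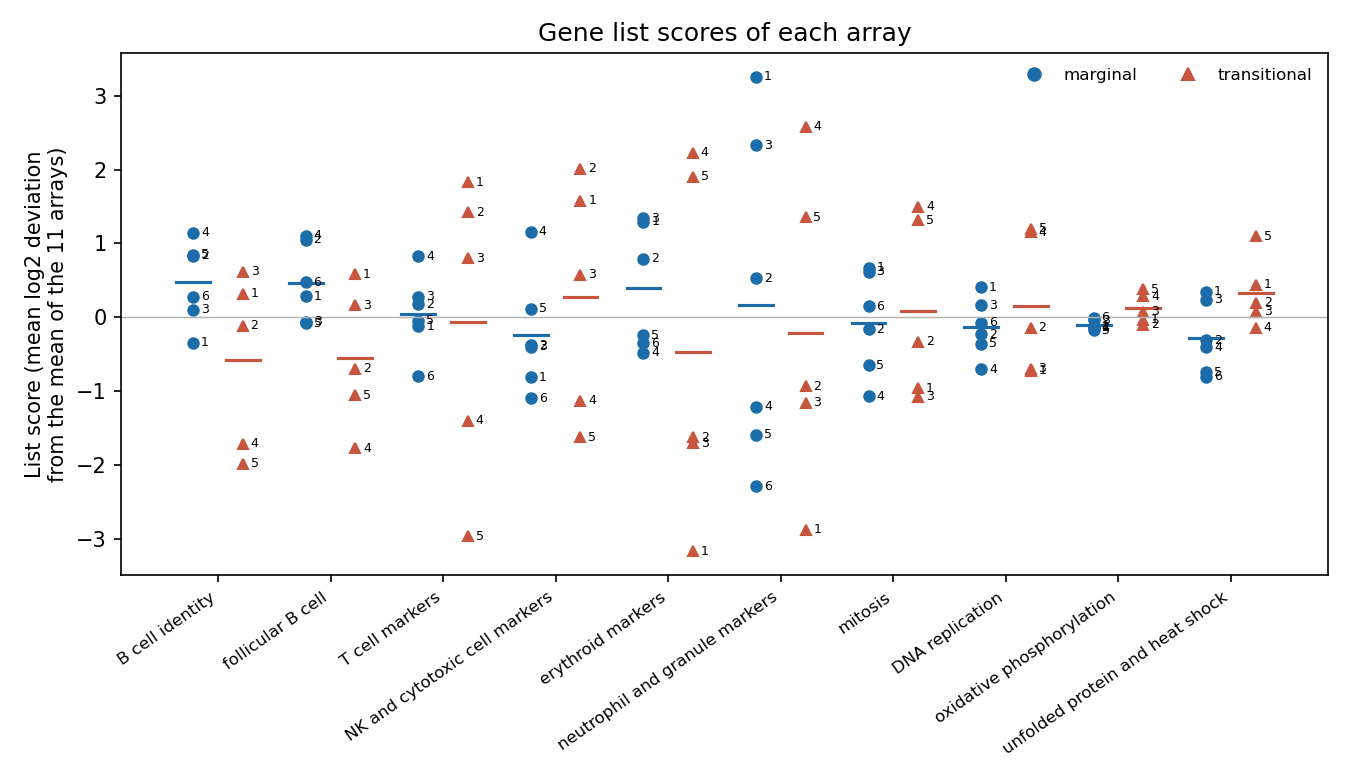
Score of 10 gene lists (mean log2 deviation of the members from the mean of the 11 arrays, vertical axis) on each array, with circles for the 6 marginal and triangles for the 5 transitional lymphomas, the sample number beside each point and a horizontal bar at each class mean. Transitional 4 and 5 have the lowest B cell identity scores, −1.71 and −1.98, and the highest mitosis scores, 1.49 and 1.31.

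Genes of DNA replication and cell division were highest on transitional 4 and 5, where erythroid scores were also highest, at 2.22 and 1.91. The mitosis score followed the erythroid score over the 11 arrays (Pearson r = 0.855, permutation p = 0.00107; Spearman rho = 0.891, permutation p = 0.00059; r = 0.830 without transitional 1 and 4), 1 of 6 such relations, with adjusted permutation p = 0.0029 and 0.00177. The mean log2 difference between classes was 0.29 for DNA replication (20 of 22 members higher; camera adjusted p = 0.00184) and 0.16 for mitosis (22 of 27 members higher; adjusted p = 0.0425), and with an estimated correlation both gave adjusted p = 0.857. Rfc3, a subunit of the clamp loader, differed by 0.59 (SE 0.32), the origin recognition gene Orc6 by 0.61 (SE 0.42), and the spindle checkpoint genes Mad2l1 and Bub1 by 0.60 (SE 0.39) and 0.60 (SE 0.58). Mitosis scores were 1.49 on transitional 4 and 1.31 on transitional 5, between −1.08 and −0.33 on the other transitional arrays, and between −1.07 and 0.67 on the marginal arrays. Without transitional 4 and 5 the direction turned, to −0.72 for mitosis (adjusted p = 1.92e-08) and −0.38 for DNA replication (adjusted p = 8.58e-05), each with adjusted p = 0.575 with an estimated correlation. With the erythroid score as a covariate the means were instead 0.61 for mitosis (adjusted p = 1.52e-10) and 0.62 for DNA replication (adjusted p = 2.73e-12), with adjusted p = 0.469 and 0.386 with an estimated correlation. Leaving out transitional 4, transitional 5 or marginal 4 alone gave mitosis means of −0.19, −0.15 and −0.039 and DNA replication means of 0.040, 0.032 and 0.17 (adjusted p = 0.491, 0.53 and 0.0501), and the mitosis call was also lost without marginal 2 (adjusted p = 0.0616) or marginal 5 (mean 0.045, adjusted p = 0.294). The mitosis call was lost as well with quantile normalization, median scaling, no filter and the upper 40% by mean (adjusted p = 0.211, 0.156, 0.131 and 0.0558). The means there, 0.16, 0.28, 0.16 and 0.16, were not smaller. Among animals that failed to nest both calls were lost, with means of −0.15 for mitosis (adjusted p = 0.897) and 0.19 for DNA replication (adjusted p = 0.0960). The E2F and G1/S list had a mean of −0.0011 (adjusted p = 0.473), with Cdk4 at 0.31 (SE 0.18) and Ccnd1 at −0.72 (SE 0.45). Its mean was −0.62 (adjusted p = 1.31e-06) with transitional 4 and 5 left out, 0.19 (adjusted p = 0.0426) without transitional 1, and 0.32 (adjusted p = 9.51e-05) with the erythroid score as a covariate. These calls gave adjusted p = 0.575, 0.754 and 0.440 with an estimated correlation. The core histones list, which as written also holds linker histone genes and Slbp, not a histone gene, had 4 tested genes. Its mean was 0.06 (adjusted p = 0.473), with H2az1 at 0.28 (SE 0.27) and H2ax at −0.20 (SE 0.48). The mean was −0.57 (adjusted p = 0.0285) with transitional 4 and 5 left out but 0.37 (adjusted p = 0.0419) with the erythroid covariate. Both calls were lost with an estimated correlation (adjusted p = 0.575 and 0.469).

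Mitochondrial respiratory chain genes had a higher mean in transitional lymphomas for all 27 tested members of the oxidative phosphorylation list, by a mean log2 difference of 0.22 (camera adjusted p = 2.48e-09; adjusted p = 0.382 with an estimated correlation). Ndufa2, a subunit of complex I, had a signal of 3371 ± 686 in marginal (SD, n = 6) and 4585 ± 249 in transitional lymphomas (SD, n = 5), with each transitional array above every marginal array, and the complex IV subunit Cox6c differed by 0.49 (SE 0.19). The score of this list was 0.28 on transitional 4 and 0.38 on transitional 5 and at most 0.08 on any other array, and without those 2 arrays the mean was 0.09 (adjusted p = 0.250). All 18 tested members of the unfolded protein and heat shock list were higher in transitional lymphomas, by 0.61 on average (camera adjusted p = 7.92e-07; adjusted p = 0.382 with an estimated correlation). The inducible Hsp70 genes had the largest differences, 3.24 (SE 1.07) for the Hspa1b probe set with the highest mean log2 signal and 3.25 (SE 1.23) for Hspa1a, and the list median was 0.30. Signal at this Hspa1b probe set ran from 1473 to 15500 in transitional lymphomas, at or below 428 in marginal 2, 4, 5 and 6, and was 5657 in marginal 1 and 2440 in marginal 3. Cholesterol synthesis genes were higher in 9 of 13 members, by 0.21 (camera adjusted p = 0.00935; adjusted p = 0.382 with an estimated correlation), with Idi1 at 0.81 (SE 0.30) and Nsdhl at 0.28 (SE 0.15). This call was lost on leaving out marginal 1, 3 or 5 or transitional 2, at an adjusted p of 0.0504 to 0.0678, and with the erythroid score as a covariate (mean 0.18, adjusted p = 0.0963). The exact permutation test of list scores over all splits of the arrays gave its smallest p for oxidative phosphorylation (p = 0.0130, two-sided exact), and p = 0.481 after Benjamini-Hochberg adjustment of these exact values over the lists.

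The remaining lists of signalling and growth did not pass camera over all arrays. Immediate early genes had a mean log2 difference of 0.44 (12 of 17 members higher; adjusted p = 0.0666), with Jun at 1.32 (SE 0.82) and Ier3 at 1.15 (SE 0.83), and the score was 2.10 on marginal 1 and 1.77 on transitional 5. This mean was 0.89 (adjusted p = 1.3e-07) without marginal 1 and 0.052 without transitional 5, and the list was also called without transitional 1, 2 or 4 (adjusted p = 0.0426, 0.0402 and 0.00749) among animals that failed to nest (0.85, adjusted p = 1.24e-05) and with the erythroid score as a covariate (0.64, adjusted p = 0.02995). The MYC and ribosome biogenesis list had a mean of 0.07 (adjusted p = 0.204), with Nop58 at 0.40 (SE 0.29) and Polr1b at −0.43 (SE 0.32), and was called at 0.17 without marginal 6 (adjusted p = 0.00394) and 0.15 among animals that failed to nest (adjusted p = 0.00585). Ribosomal protein genes had a mean of −0.02 and turned sign under quantile normalization and median scaling (adjusted p = 0.473 as deposited), with Rpl14 at 0.36 (SE 0.20) and Rpl12 at −0.84 (SE 0.55). They were called higher with transitional 4 and 5 left out (0.21, adjusted p = 0.00124) and without marginal 4 (0.046, adjusted p = 0.0416) or transitional 5 (0.064, adjusted p = 0.0443). Glycolysis and hypoxia genes had a mean of 0.0050 (adjusted p = 0.345), with Ldha at 0.33 (SE 0.19) and Ndrg1 at 0.71 (SE 0.45), and were called without marginal 1 (0.09, adjusted p = 0.0431). The means were −0.14 for apoptosis regulators (adjusted p = 0.289; Bcl2l11 −0.70, SE 0.30, and Bbc3 0.64, SE 0.36) and 0.09 for p53 targets (adjusted p = 0.314; Sesn1 −0.36, SE 0.20, and Sesn2 0.64, SE 0.35). NF-kB targets were lower in 11 of 14 members, by −0.29 (adjusted p = 0.320), with Nfkbie at −0.75 (SE 0.47) and Cd40 at −0.99 (SE 0.66), and their mean was 0.47 (adjusted p = 0.0120) without transitional 4 and 5 but −0.64 (adjusted p = 0.0106) with the erythroid score as a covariate. The interferon response list had a mean of −0.07 and a median of 0.02 (adjusted p = 0.284), with the sensor Ifih1 at 0.55 (SE 0.19) and Rsad2 at −1.87 (SE 0.73). Its mean also turned sign under quantile normalization and median scaling. The interferon list turned and was called higher with transitional 4 and 5 left out (0.50, adjusted p = 9.56e-05) and without transitional 4 (0.13, adjusted p = 0.0216) or transitional 5 alone (0.16, adjusted p = 0.0176). None of the calls made for these signalling and growth lists held with an estimated correlation (smallest adjusted p = 0.4075). Camera pointed up for the interferon, ribosomal and E2F lists although their means were negative. The median over all tested probe sets was −0.06 as deposited, −0.00052 after quantile normalization and 0.06 after median scaling.

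Transcripts of red cell precursors spanned 5.39 log2 units of list score between animals, with transitional arrays at both ends. All 22 tested members of the erythroid list had a lower mean in transitional lymphomas, by a mean log2 difference of −0.87 (camera adjusted p = 0.0086; adjusted p = 0.857 with an estimated correlation). Slc4a1, the red cell anion exchanger, had a signal between 455 and 2167 on transitional 1, 2 and 3, of 14927 and 12497 on transitional 4 and 5, and between 6201 and 12891 on the marginal arrays. Alas2, the erythroid enzyme of haem synthesis, ran from 233 on transitional 1 to 18342 on transitional 4. The erythroid score was 2.22 on transitional 4, 1.91 on transitional 5, 1.34 on marginal 3 and 1.29 on marginal 1, and −3.16, −1.62 and −1.70 on transitional 1, 2 and 3. With transitional 4 and 5 left out the mean difference was −2.56 (adjusted p = 5.44e-35; adjusted p = 0.363 with an estimated correlation). The call was lost on leaving out transitional 1 (mean −0.19, adjusted p = 0.885), transitional 2 or 3 (adjusted p = 0.338 and 0.298) or marginal 1 or 3 (adjusted p = 0.118 and 0.152), and with sex as a covariate (adjusted p = 0.138). Neutrophil and granule genes had a mean difference of −0.38 (adjusted p = 0.721) with scores from 3.26 on marginal 1 to −2.87 on transitional 1, and Csf3r and Mmp9 differed by −0.91 (SE 0.73) and −0.75 (SE 0.98). This mean was 0.29 without transitional 1, 0.24 without marginal 1, 0.054 without marginal 3 and −1.07 (adjusted p = 0.0202) without transitional 4. It was −1.64 (adjusted p = 2.6e-05) among animals that failed to nest, and −1.82 (adjusted p = 9.56e-05) with transitional 4 and 5 left out, but 0.58 (adjusted p = 0.02995) with the erythroid score as a covariate. None of these neutrophil calls held with an estimated correlation (smallest adjusted p = 0.575).

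The list scores of natural killer and T cells were highest in transitional 1 and 2, which does not hold for each gene of lymphocytes. Natural killer and cytotoxic cell genes were higher in transitional lymphomas for 9 of 11 members, by a mean log2 difference of 0.52 (camera adjusted p = 0.0425; adjusted p = 0.857 with an estimated correlation). Ifng differed by 1.71 (SE 0.94) and Gzmb, a cytotoxic granule protease, by 1.48 (SE 0.91), with Gzmb at 4333 on transitional 2 and at most 612 on the other arrays. The score of this list was 1.58 on transitional 1 and 2.01 on transitional 2, and −1.13 and −1.63 on transitional 4 and 5. Leaving out transitional 4 and 5 gave a mean of 1.61 (adjusted p = 7.62e-08; adjusted p = 0.4075 with an estimated correlation). The call was lost on leaving out transitional 1, 2 or 3 or marginal 1, 3 or 6, with means of 0.084 (without transitional 2) to 0.48 and an adjusted p of 0.0918 to 0.488. It was also lost with an offset of 1 (mean 0.40, adjusted p = 0.143), median scaling (0.61, adjusted p = 0.109) and no filter (0.42, adjusted p = 0.116). The same held in the upper 40% by mean (0.24, adjusted p = 0.541), among animals that failed to nest (0.67, adjusted p = 0.0648) and with sex as a covariate (0.31, adjusted p = 0.301). With the erythroid score as a covariate the mean was 0.0055 (adjusted p = 0.783). T cell markers had a mean of −0.11 (adjusted p = 0.718), with scores of 1.83 and 1.42 on transitional 1 and 2 and −2.96 on transitional 5. Camera pointed up for this list although its mean and median were negative. Its members with the smallest p were Zap70 at 0.56 (SE 0.32) and Cd2 at −0.70 (SE 0.83), and marginal 1 stood apart from its class for both. Without transitional 4 and 5 the T cell mean was 1.37 (adjusted p = 2.89e-11), and without transitional 5 alone 0.63 (adjusted p = 0.000176). The mean also turned, with no call, at an offset of 64 (0.011), with quantile normalization (0.0014) and without marginal 4 (0.040). Its direction thus did not depend on transitional 4 and 5 alone. Neither T cell call held with an estimated correlation (adjusted p = 0.363 and 0.761).

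Markers of further cell types did not pass camera over all arrays with the filter on dim probe sets. With no filter dendritic cell genes (mean −0.44, adjusted p = 0.04996), fibroblast and matrix genes (0.34, adjusted p = 0.0404) and pancreatic acinar genes (0.45, adjusted p = 0.0295) were called. Macrophage and monocyte genes had a mean log2 difference of 0.16 (adjusted p = 0.257), with the complement genes C1qa at 1.01 (SE 0.85), where marginal 2 stood above its class, and C1qb at 0.67 (SE 0.59). Dendritic cell genes were lower in 9 of 11 members, by −0.43 (adjusted p = 0.172), with Cst3 at −0.69 (SE 0.27) and Cd209a at −1.26 (SE 0.66). They were also called without marginal 6 (−0.59, adjusted p = 0.0346), among animals that failed to nest (−0.72, adjusted p = 0.0078) and with sex as a covariate (−0.62, adjusted p = 0.0222). Megakaryocyte and platelet genes had a mean of −0.06 and a median of 0.0069 (adjusted p = 0.473), with Gp5 at 0.46 (SE 0.37) and Itga2b at 0.42 (SE 0.35), and were called without transitional 1 (0.31, adjusted p = 0.0426). Stem and progenitor genes had a mean of −0.15 (adjusted p = 0.889), with Runx1 at −0.42 (SE 0.57) and Flt3 at −0.21 (SE 0.30). Mast cell and basophil genes had a mean of −0.50 (adjusted p = 0.473), with Mcpt8 at −1.12 (SE 0.82) and Hdc at −0.85 (SE 0.68), and were called among animals that failed to nest (−1.0, adjusted p = 0.00716). Endothelial genes had a mean of 0.15 (adjusted p = 0.345), with Egfl7 at 0.81 (SE 0.35), where marginal 5 stood below its class, and Pecam1 at −1.12 (SE 0.51). Genes of fibroblasts and extracellular matrix had a mean of 0.16 (adjusted p = 0.473), with Col1a2 at 0.91 (SE 0.73), where transitional 2 stood above its class, and Col6a2 at −0.29 (SE 0.33). Follicular dendritic and lymphoid stroma genes had a mean of 0.15 (adjusted p = 0.473), with Cr2 again at −1.75 and Fcgr2b at −0.47 (SE 0.42). Both stromal lists had their highest score on transitional 2, at 1.72 and 2.71, and without it their means were −0.25 and −0.57. The endothelial and macrophage means also turned without it, to −0.18 and −0.22, and macrophage genes were called higher without marginal 2 (0.35, adjusted p = 0.0153) or transitional 1 (0.49, adjusted p = 0.00446) and lower among animals that failed to nest (−0.46, adjusted p = 0.0237). The pancreatic acinar list, measured by 4 genes, had a mean of 0.33 (adjusted p = 0.284), with Cela1 at 0.91 (SE 0.60) and Prss2 at 0.18 (SE 0.39), and was also called without transitional 1 (0.605, adjusted p = 0.0426). No call for these markers held with an estimated correlation (smallest adjusted p = 0.477).

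Across single genes, St3gal6, a sialyltransferase, was higher in transitional lymphomas by 1.25 (SE 0.28), with a signal of at least 1417 on all 5 transitional arrays and at most 1294 on all marginal arrays. Angptl4, an inhibitor of lipoprotein lipase, differed by 1.27 (SE 0.37), and the Hspa1b probe set with the smallest p by 3.52 (SE 1.12). The other genes with the smallest p among those higher were Etf1, Nxph3, Ddx39a, Eny2 and Atg12, at 0.50 to 0.92. Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, differed by −0.86 (SE 0.20), with a signal of at most 795 on the transitional and at least 982 on the marginal arrays. Notch2, a receptor needed by marginal zone B cells, differed by −1.02 (SE 0.26), and Atp1b1, a subunit of the sodium pump, by −1.82 (SE 0.50). Heatr6 at −0.93 (SE 0.20), Ttc28 at −1.19 (SE 0.31), Cox15 at −0.91 (SE 0.25), the chromatin remodelling subunit Bptf at −1.12 (SE 0.33) and Ebf1 completed those lower. None of these genes passed the test. Of 13576 probe sets, 0 passed adjusted p 0.05 in limma (smallest adjusted p = 0.999), and 454 lay below an unadjusted p of 0.05, 129 higher and 325 lower, where 678.8 are expected by chance. That balance depended on the scaling, with 186 higher and 238 lower after quantile normalization and 222 higher and 179 lower after median scaling, and was 104 higher and 54 lower among animals that failed to nest. Of the members of the 37 tested lists, 0 passed when adjusted over the list alone and 0 when adjusted over all probe sets. In data simulated with independent noise the fit recovered 26 of 100 probe sets changed 2-fold and 69 of 100 changed 4-fold. On the residuals of these arrays, where the estimates held no sampling error, it recovered 5 and 54. Most 2-fold differences were thus not recovered in either simulation.

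**Figure D2:**
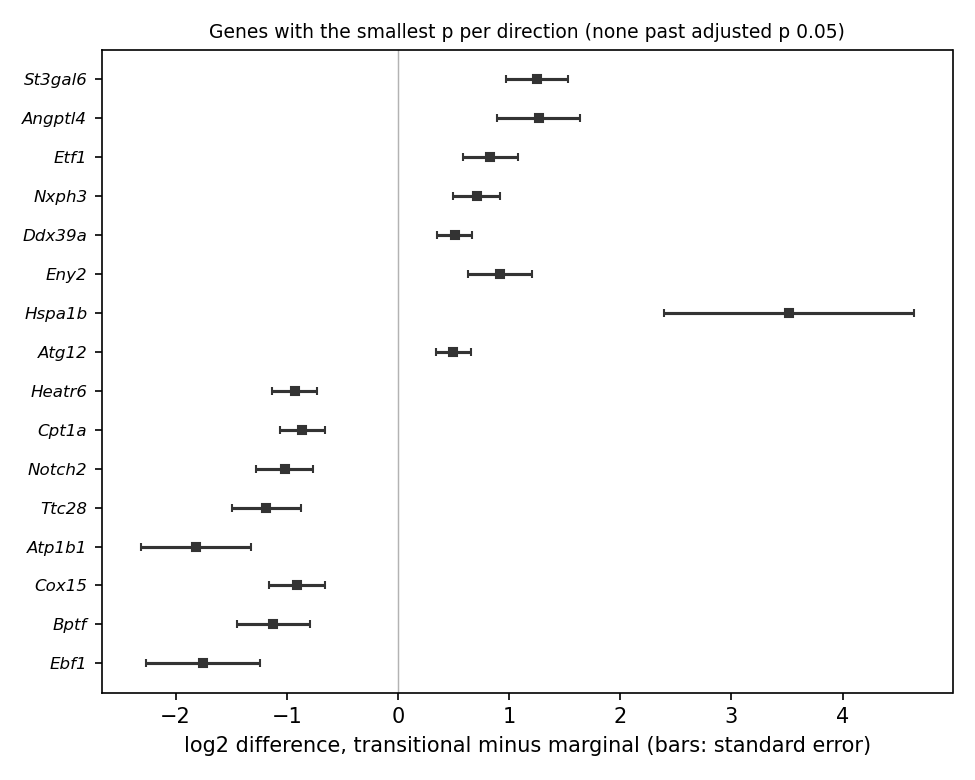
Log2 difference between classes (transitional minus marginal, horizontal axis) for the 8 genes of each direction with the smallest p, with squares for the estimate and bars for its standard error over 6 marginal and 5 transitional arrays. The estimates run from −1.82 for Atp1b1 to 3.52 for Hspa1b, and none passed adjusted p 0.05.

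Spleen grade was taken as a rank from 1 for marginal to 5 for severe enlargement and tested as a linear trend over the 11 arrays. The serine hydroxymethyltransferase gene Shmt2 was higher with grade by 0.39 per grade (SE 0.10) in log2, the chromatin remodeller Atrx by 0.29 (SE 0.08), Ndufa2 by 0.21 (SE 0.06), Rhbdd3 by 0.76 (SE 0.22) and an H2-D1 probe set by 0.55 (SE 0.15), the last with signals from 44.7 on transitional 3 to 392.1 on transitional 2. This dim probe set lay at 147.8 or above on the 5 arrays where another H2-D1 probe set was bright, marginal 5 and 6 and transitional 1, 2 and 5, and at 78.1 or below on the other 6. The 4 bright H2-D1 probe sets, at 1203 to 27106, did not part the arrays in this way and were each lowest on transitional 5. Lower with grade were Rab31, a small GTPase, by −0.48 per grade (SE 0.11), the C-type lectin gene Cd209a by −0.76 (SE 0.19), Krt80 by −0.37 (SE 0.10), Tppp3 by −0.59 (SE 0.17) and Kctd20 by −0.24 (SE 0.07). None of them passed the limma test, in which 0 of 13576 probe sets reached adjusted p 0.05 and 292 an unadjusted p of 0.05, 132 higher and 160 lower. With class in the model, 0 passed and 298 lay below an unadjusted p of 0.05. The count of 0 with class in the model depended on transitional 3, the only transitional animal with a mild grade. Without it 1145 probe sets passed, and without transitional 1 the count was 1. With transitional 3 left out, the transitional arrays were 4 and 5 at moderately severe and 1 and 2 at severe. Grade within that class was then not separated from whatever else set transitional 4 and 5 apart.

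Among the lists, tested against grade by camera only after the counts of genes had been seen, erythroid genes had a mean slope of −0.44 per grade, neutrophil and granule genes −0.59, B cell identity genes −0.29 and oxidative phosphorylation genes 0.05. Camera with a preset correlation called 15 of 37 lists, 7 up and 8 down, including these (adjusted p = 4.28e-06 for erythroid, adjusted p = 2.49e-05 for neutrophil and for B cell genes, and adjusted p = 0.000258 for oxidative phosphorylation). With an estimated correlation 0 lists passed (smallest adjusted p = 0.562). With class in the model, neutrophil genes had a slope of −1.0 (adjusted p = 5.89e-09), immediate early genes −0.50, erythroid genes −0.41, mast cell genes −0.56 and MYC and ribosome biogenesis genes 0.10, and these 5 lists were called. Here too 0 passed with an estimated correlation (smallest adjusted p = 0.853).

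Immunoglobulin transcripts were examined because all tumours were recorded as oligoclonal. The spread of immunoglobulin probe sets between animals of 1 class was a median of 4.21 times that of probe sets of like level, and 34 of the 41 tested probe sets lay above the 90th percentile of such neighbours. An Igk probe set ran from 4.5 on transitional 2 to 19023 on transitional 1, and an Ighm probe set from 56.2 on transitional 2 to 32928 on transitional 1. Igkv4-72 ran from 42.7 on transitional 2 to 14795 on transitional 1, and Igkv15-103 and Igkv9-120 were likewise lowest on transitional 2, at 35.1 and 54.5. Marginal 5 and 6 lay below the other marginal arrays for each of these 5 probe sets, with Igkv15-103 at 449.8 and 37.1. These probe sets were picked for their range, and not all brighter ones followed them. A brighter Ighm probe set did, from 180.6 on transitional 2 to 36483 on transitional 1. An Igha probe set, brighter still, was at 1542 on transitional 2 and 23406 on transitional 1, with 768.8 on marginal 6. Others among the brightest did not. The brightest Ighm probe set was at 36542 on transitional 2 and 26394 on transitional 1. A bright probe set of several kappa chain genes was at 33838 on transitional 2 and 34962 on transitional 1. Between classes 0 of the 41 passed the limma test and 2 lay below an unadjusted p of 0.05.

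**Figure D3:**
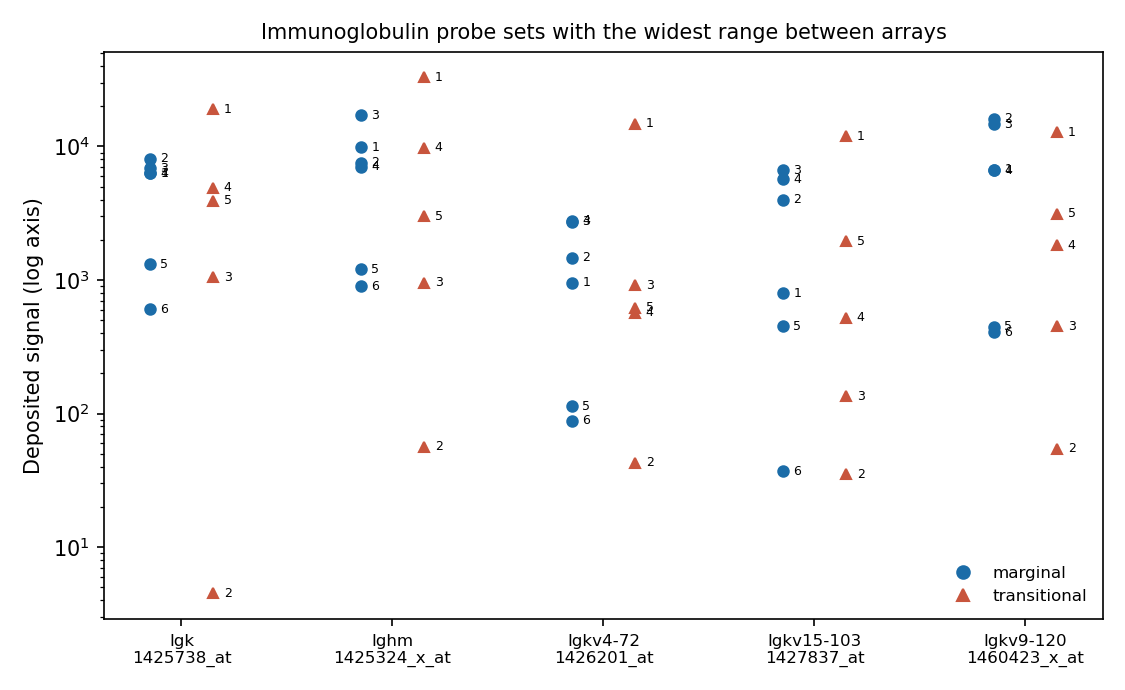
Deposited signal (vertical axis, log scale) of 5 immunoglobulin probe sets, taken by widest range between arrays with 1 per gene symbol. Circles mark marginal and triangles transitional lymphomas, with the sample number beside each point. Transitional 2 is the lowest of the 11 arrays for all 5 probe sets, and transitional 1 the highest for 4 of them.

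The median correlation between arrays was 0.895 within marginal, 0.772 within transitional and 0.880 between the classes. The first principal component took 46.5% of the variance and set transitional 4 and 5, at −89.1 and −94.6, apart from the other arrays, at −41.0 to 54.2. The median signal was 133 ± 9.02 in marginal (SD, n = 6) and 123 ± 20.4 in transitional lymphomas (SD, n = 5), with p = 0.310 in a two-sided exact permutation test over all splits. The lowest medians were those of transitional 5 and 4, at 98.8 and 108, with marginal 6 next at 119. That test compared the classes and not this pair with the rest. The ratio of 3-prime to 5-prime signal, which rises with RNA degradation, was 0.706 ± 0.0686 and 0.678 ± 0.0343 for Gapdh (exact p = 0.530) and 1.18 ± 0.0797 and 1.22 ± 0.134 for beta-actin (exact p = 0.522), with marginal 5 above the rest of its class for both. The 3 tests gave p = 0.530 each after Benjamini-Hochberg adjustment of the exact values.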

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

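The tests of RNA degradation, of a lower B cell share, of cells that express H2-D1 and of sex were chosen only after the result was seen, and the patterns themselves were noticed in these data. A sample was marked where its gap to the nearest array of its class, as a share of the range of that class, was larger than chance gives in 95% of groups. Of 282 groups examined 11 were marked, where 14.1 are expected by chance.

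Transitional 2 stood above its class for the lymphoid stroma score, at 2.71 against −0.28 for the next array (gap 0.854 of the range), for the extracellular matrix score, at 1.72 against −0.04 (gap 0.776), and for Col1a2, at 10.78 against 7.05 in log2 signal (gap 0.731). Marginal 1 stood above its class for the immediate early score, at 2.10 against −0.21 (gap 0.694), and for Zap70, at 8.91 against 7.58 (gap 0.701), and below it for Cd2, at 9.70 against 11.33 (gap 0.675). Irf4 was lowest on transitional 4, at 6.86 against 9.56 (gap 0.874). C1qa was highest on marginal 2, at 10.25 against 8.54 (gap 0.665), and Egfl7 lowest on marginal 5, at 5.06 against 6.18 (gap 0.692). Marginal 5 had the highest ratio of 3-prime to 5-prime signal of its class for Gapdh, at 0.839 against 0.694 (gap 0.727), and for beta-actin, at 1.33 against 1.17 (gap 0.744).

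Erythroid and granulocyte transcripts differed widely between animals of 1 class, with erythroid scores from −3.16 to 2.22 among transitional lymphomas. RNA degradation was argued against by the controls for the transferrin receptor, itself a gene of the erythroid list. Their SD between arrays was 1.92 at the 3-prime and 2.01 at the 5-prime end, a ratio of 0.953. Degradation as the source would leave the 3-prime end far steadier than the 5-prime end. This covers that gene alone. A lower B cell share with all other cell types raised alike was argued against because T cell scores fell as erythroid scores rose (Spearman rho = −0.809, permutation p = 0.00368; Pearson r = −0.787, permutation p = 0.00342, and −0.683 without transitional 1 and 4, but 0.056 within the marginal class), and scaling because quantile normalization left the range of scores at 1.01 times its size. Spleen grade stays open (rho = −0.178, permutation p = 0.598; r = −0.352, permutation p = 0.290, and −0.279 without transitional 1 and 4). More or fewer red cell and granulocyte precursors in the sampled tissue may underlie the pattern, and the tissue is not given in the sources used here.

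An H2-D1 probe set was bright on 5 arrays, at 2504 to 10139 on marginal 5 and 6 and transitional 1, 2 and 5, and dim on 6, at 129 to 345. More or fewer cells that express H2-D1 were argued against, since the other 7 tested H2-D1 probe sets had a median rho of 0.0818 with it, although 3 dim ones among them followed it at 0.736 to 0.891 while the 4 bright ones had 0 to 0.0818. Sex was argued against, since 3 animals were out of place between the bright arrays and those with Y-linked transcripts. A sequence or haplotype difference linked to the H2 region may be the source and stays open, since 2 of the 50 probe sets that followed it best lie near H2-D1, H2-Eb1 and Vars, a share of 4% against 1.10% of all tested (Fisher exact p = 0.105, one-sided). No biological explanation from the design was tested.

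Hspa1a and Hspa1b, read by 4 probe sets, had a mean log2 signal of 11.73 ± 1.52 in transitional (SD, n = 5) and 8.32 ± 2.60 in marginal lymphomas (SD, n = 6), a difference of 3.42 (exact permutation p = 0.0346, not adjusted and tested because it was large). That 1 animal made the difference was argued against, since it was 2.83 without transitional 5, the lowest on leaving out any array, and 4.17 without marginal 1, the highest. Stress of the tissue at collection may contribute and stays open, since the Hspa1 mean followed the immediate early score (Spearman rho = 0.8, permutation p = 0.00491; Pearson r = 0.738, permutation p = 0.00773, and 0.705 without marginal 1 and transitional 5). Over the relations with spleen grade and with the immediate early score, taken as 1 family, the adjusted p = 0.00982 for this rho and adjusted p = 0.0155 for this r. Severity class stays among the open explanations.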

How the results depend on the processing

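The fits without transitional 4 and 5, with the erythroid score or sex as a covariate and with unordered grades were chosen only after the result was seen. The class count at adjusted p 0.05 stayed at 0 and the class list count at 7 to 13 in every other setting run, except as given here, and the cause of each change was not tested unless the setting itself removed arrays or genes. Counts at an unadjusted p of 0.05 (454 for class, 292 for grade, 298 for grade with class in the model) were 869, 709 and 792 with no filter on dim probe sets, and 185 and 183 for the grade fits in the upper 40% by mean. The class count was 158 (104 higher, 54 lower) among animals that failed to nest (2 marginal and 5 transitional arrays), 860 with array weights and 1079 without transitional 4 and 5, where the grade counts were 1206 and 552. With the erythroid score as a covariate it was 2845, and 241 passed adjusted p 0.05. With unordered grades 2016 passed.

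Camera with a preset correlation called 9 lists as set out and 14 without transitional 4 and 5. With an estimated correlation, run beside the preset one in each of these settings except array weights and mostly chosen after the results were seen, it called 0 in every setting (smallest adjusted p = 0.128, in the upper 40% by mean). Fry called 0. Among animals that failed to nest 5 means turned, with mitosis at −0.15 and macrophages at −0.46 (each 0.16 over all arrays), and 6 lists gained a call: macrophage, neutrophil, immediate early, MYC, dendritic and mast cell. Without transitional 4 and 5 the means of 14 lists turned. Those that passed were class I antigen presentation 0.61, interferon response 0.50, NF-kB targets 0.47, DNA replication −0.38, mitosis −0.72, ribosomal proteins 0.21, T cell markers 1.37 and core histones −0.57, and the others were class II, plasma cell, B1 and marginal zone, pro-B and pre-B, germinal centre and apoptosis. E2F and neutrophil lists gained a call there. With the erythroid covariate 7 lists gained a call: E2F and G1/S at 0.32, neutrophil at 0.58, class I, class II, NF-kB, immediate early and core histones, while natural killer and cholesterol were lost. None of the 13 calls under this covariate held with an estimated correlation (adjusted p = 0.440 for E2F and 0.677 for neutrophil, smallest adjusted p = 0.386). The erythroid list under its own covariate is 0 by construction and was left out.

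Leaving out 1 array at a time gave class counts at an unadjusted p of 0.05 from 237 (without transitional 5) to 718 (without transitional 1), and 299 without marginal 4. Grade counts ran from 195 (without marginal 2) to 514 (without transitional 1). With class in the model they ran from 215 to 4022, and from 0 to 1145 at adjusted p 0.05, both highest without transitional 3. Means ran from −0.30 to 0.16 for interferon response, −0.24 to 0.19 for E2F and G1/S, −0.19 to 0.45 for mitosis, −0.12 to 0.066 for ribosomal proteins, −0.59 to 0.63 for T cell markers and −0.34 to 0.31 for megakaryocytes. Over these fits the means of 19 of 37 lists turned sign at least once, and 15 lists not called over all arrays were called. Beside class II, immediate early, macrophage, BET, plasma cell and neutrophil lists, these were glycolysis without marginal 1, MYC and dendritic without marginal 6, E2F, megakaryocyte and acinar without transitional 1, interferon without transitional 4 or 5, ribosomal without marginal 4 or transitional 5, and T cell without transitional 5. The class difference in the beta-actin ratio of 3-prime to 5-prime signal ran from −0.0091 to 0.077.

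The sample number as a block, where marginal 6 has no partner and adds nothing to the difference, gave a class count of 0 (315 at an unadjusted p of 0.05) and 10 lists. Without marginal 6 alone these were 0 (605) and 10, with natural killer lost and MYC and dendritic gained in both. The numbers pair nothing in the labels. With the class mean taken from each probe set, the deviations of same-number samples had correlations of −0.45 to −0.09. By this measure 0 of 5 transitional samples correlated best with the marginal sample of their own number. Of 92 class differences of named genes (91 with an offset of 1 and 67 in the upper 40%), 0 passed in any setting except 11 with the erythroid covariate. Those 11 include Slc4a1 (limma adjusted p = 0.0463), a member of the list that forms this covariate. The sign of 11 turned without transitional 4 and 5, and of at most 5 in any other setting. Among animals that failed to nest the calls for DNA replication (adjusted p = 0.0960) and natural killer cells (adjusted p = 0.0648) were lost, and with sex as a covariate those for natural killer (adjusted p = 0.301) and erythroid genes (adjusted p = 0.138). Dim probe sets are limited by their signal over background, which the offset of 16 damps.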

Other observations

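The relations between list scores, the transcripts that were bright in some animals and far dimmer in others, and the fits with a covariate, with unordered grades and with an interaction were chosen only after the result was seen, while the count of other splits of the samples was planned for the class comparison.

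Several cell types moved with the erythroid score over the 11 arrays, in 6 relations tested by permutation and adjusted together. Neutrophil and granule scores were higher where erythroid scores were higher (Pearson r = 0.852, adjusted permutation p = 0.0029; Spearman rho = 0.773, adjusted permutation p = 0.00863), with r = 0.776 without transitional 1 and 4, the arrays farthest from the median, and r = 0.956 within the marginal class. Mitosis scores followed as well (r = 0.855, adjusted permutation p = 0.0029; rho = 0.891, adjusted permutation p = 0.00177; r = 0.830 without those arrays). Natural killer scores ran the other way (r = −0.836, adjusted permutation p = 0.0029, and rho = −0.845, adjusted permutation p = 0.00388), with r = −0.785 without those arrays and −0.453 within the marginal class. Class II antigen presentation did so too (r = −0.765, adjusted permutation p = 0.00738, and rho = −0.891, adjusted permutation p = 0.00177), with r = −0.788 without those arrays and −0.723 within the marginal class. T cell scores had r = −0.787 (adjusted permutation p = 0.00513) and rho = −0.809 (adjusted permutation p = 0.00552), but r = 0.056 within the marginal class. B cell identity did not pass (r = −0.581, adjusted permutation p = 0.0612; rho = −0.573, adjusted permutation p = 0.0714; r = −0.542). The raw permutation p were 0.00117, 0.00107, 0.00145, 0.00615, 0.00342 and 0.0612 for r and 0.00719, 0.00059, 0.00194, 0.00048, 0.00368 and 0.0714 for rho, in the order named.

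Some transcripts were bright in a few animals and far dimmer in the rest. Ms4a4b, a membrane protein gene of lymphocytes, had signals of 1825 on marginal 5, 2749 on marginal 6 and 3430 on transitional 3, and at most 11.9 on the other arrays. The chemokine gene Cxcl2 was 1915 on marginal 1 and 5908 on transitional 5, and at most 101.2 elsewhere. The granule protease genes Ctsg and Prtn3 and the granulocyte precursor gene Ms4a3 were bright on marginal 1 and 3 and transitional 4 and 5, with Ctsg at 5850 to 11381 there and at most 472 elsewhere, the highest being marginal 2. The Wnt receptor gene Fzd6 was 672 on marginal 5 and 654 on transitional 3, and at most 64.2 elsewhere. Y-linked Eif2s3y was 279.8 or more on marginal 2 and transitional 1, 2 and 5 and at most 4.2 elsewhere, so 1 of 6 marginal and 3 of 5 transitional animals read as male.

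Splits of the 11 arrays into groups of 6 and 5 bear on how far the class counts exceed chance. Of 100 splits, the real one included, 40 gave as many probe sets at an unadjusted p of 0.05 as the 454 of the classes (highest other 4854, median of the others 354). Of the same 100, 75 gave as many lists as the 9 of camera (highest other 22, median 12), so chance was not excluded for either count. At adjusted p 0.05, where the classes gave 0, 6 of the other splits called probe sets, up to 2532, which points to a structure of the samples other than class.

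A hypothesis is that variation in red cell precursors masks a class difference. With the erythroid score as a covariate 241 probe sets of 181 genes passed, 28 higher and 213 lower in transitional lymphomas. Only 1 of 100 splits, the real one, gave as many (highest other 23). Each array kept its score in these splits, so a split that ran along with the score could give few calls. The score came from the same arrays and was chosen after the planned count of 0, so chance was not excluded. Those lower included Foxp1 at −1.85 and Ebf1 at −2.15, and those higher Oaf at 1.18 and Acp1 at 1.03, named after their values were seen. Camera called 13 lists under this covariate, and 0 with an estimated correlation (smallest adjusted p = 0.386). The other class models tried beside it, without transitional 4 and 5 (1079 at an unadjusted p of 0.05) and with sex as a covariate (324), passed 0 probe sets. The interaction of grade and class in limma also passed 0 (1462 at an unadjusted p of 0.05, smallest adjusted p = 0.138). It tests whether the grade slope differs between the classes, not a class difference.

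With the 5 spleen grades as unordered groups 2016 probe sets passed, and 1 of 100 allocations of the grades, the real one, gave as many (highest other 1000). The marginal grade holds 1 array, so it has no spread of its own and is assumed to vary like the other grades, of which mild holds 4 arrays and the rest 2 each. The moderately severe grade holds only transitional 4 and 5, the arrays that stood apart on the first principal component. Of the allocations drawn, 10 kept these arrays in 1 grade and reached at most 1000, while the rest reached at most 448. The median count was 0 in both sets. The 10 were not limited to allocations with the pair alone in a grade, since the mild grade of 4 arrays could also hold it. They therefore do not show what a grade of this pair alone gives. The count of 2016 may reflect in part that this pair shared a grade. The grade and whatever else those samples had in common were not separated.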
